A study of Mus musculus with 6 samples.

How the data were processed

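Single-cell RNA libraries were made with the 10x Chromium 3' kit from cells sorted from brain, per the labels' protocols. The authors deposited, per animal, a matrix of whole-number counts of UMIs per gene and cell barcode, not normalized. Cell Ranger and the genome build mm10 are named in the submitters' processing notes, and per the file headers version 9.0.0 was used for the 8 animals of batches A and B and version 7.0.0 for the 4 animals of batch C. The 4 animals of batch A and the 4 of batch B were each sequenced as a multiplexed pool and deposited as separate matrices per the labels, and those of batch C as separate libraries. The release of the gene annotation is not given in the sources used here. All matrices listed the same 32285 genes. A classified object that the labels mention was not analysed here, so cell classes were rebuilt from the counts. The difference in Cell Ranger version, multiplexing and depth coincides with the batch, and every test between the groups was made within batches or with batch in the model.

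Cells were kept with at least 500 UMIs, at least 200 genes and under 10% mitochondrial counts, which left 36523 of 37525 barcodes. Scrublet's method, as run in scanpy 1.11.5, called 60 of these (0.164%) doublets, too few for the caller to have worked. The 60 cells were removed, and as an alternative the 5% of cells of each animal with the highest doublet scores were left out. Counts were scaled per cell and logged, 2000 highly variable genes were centred by batch, and 30 principal components were adjusted by a Harmony procedure (60 clusters, theta 2, 10 rounds) before a graph of 20 neighbours was clustered by the Leiden method at resolution 1.0 (leidenalg 0.10.2, Python 3.11.15, anndata 0.12.19). Microglia-like cells were clustered again within each batch. A cluster was taken as microglia-like by its ratio of marker scores, which had to reach 1.5, and any other cluster, or a microglial state (DAM-like, interferon-responsive or proliferating), received a name with at least 3 fixed markers among its 20 leading genes by fold. By that second rule the microglia-like cells of batches B and C, each taken whole, would have had no name, with 0 markers. The marker lists, the gene lists, the tests, the covariates, most other settings tried and the rule for named genes were fixed before the data were examined. The Harmony step, the score ratio for microglia-like clusters, and the setting apart of mixed and low-UMI clusters were chosen after clusters had been seen. Differences from the authors' own classes may therefore come from the rebuilt names.

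Raw counts were summed per animal and class, in animals with at least 20 cells of the class, because the animal and not the cell is the replicate. All 12 animals entered except for macrophage-like cells, where Sham_948 and Denerv_956 had fewer. Summed counts per animal ran from 1337247 to 13620851 for microglia-like, 57335 to 2466800 for monocyte-like, 61392 to 917825 for macrophage-like and 61529 to 6299191 for neutrophil-like cells. Genes were tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with batch, sex and group in the model and Benjamini-Hochberg adjustment at an FDR of 0.05. Genes linked to sex were left out of the counts of calls. Fold changes are log2 of denervated over sham, their SE is the fold change over the square root of the quasi-likelihood F, CPM values (counts per 1e+06 of TMM-scaled library size) are means ± SD over animals (without TMM scaling for genes of other classes), and batch differences are differences of mean log2 CPM with a prior count of 2. Because sex enters the model, a fitted fold change can lie apart from the raw difference. Sham_627 was the only male sham animal, so only among the sham animals of batch B could the sexes be compared within a group and batch. The fitted sex term, and with it the fitted group term, therefore leans on that animal. DESeq2 1.42.0 was the second tool. Coordinates are 1-based and come from the GENCODE vM21 annotation of the same build.

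The text names, in each class, the genes past the threshold with an average log2 CPM of 4 or more and the same sign in all 3 batches, up to 10 each way in microglia-like and monocyte-like cells and up to 5 elsewhere. Where fewer than 5 passed in a direction, the 5 with the smallest p in that direction at that level are named. Fixed panels of microglial and monocyte genes are given whatever their result, except that a few genes and 1 list are left out for reasons unrelated to their values, and for a described list up to 4 members with the smallest p. Gene lists, 24 in all, were tested with limma's camera (3.58.1) with a preset correlation of 0.01 where at least 5 members were measured, with the same model, and again with an estimated correlation and with fry, which asks whether a list moves one way on balance and not whether it differs from other genes. The lists cover microglial states, interferon, antigen presentation, inflammation, lipid handling, metabolism, cell cycle, dissociation, and monocyte and microglia signalling.

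Shares were compared on the logit scale, with 0.5 added to both cell counts, by an exact two-sided permutation of group within batch (216 assignments) and Benjamini-Hochberg adjustment over 10 shares. List means were tested in the same way.

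The edgeR test was checked on simulated data with the real means and library sizes and 200 genes changed, while DESeq2, fry and the permutation tests were not. Of genes changed 1.5-, 2- and 4-fold, edgeR recovered 35.8%, 73.1% and 95.5% among 13012 in microglia-like, 4.48%, 34.3% and 90.9% among 5899 in monocyte-like, 13.4%, 49.3% and 93.9% among 4576 in macrophage-like, 2.99%, 41.8% and 97.0% among 10569 in neutrophil-like, 10.4%, 61.2% and 90.9% among 9806 in DAM-like cells, 31.3%, 70.1% and 95.5% among 12344 in microglia-like cells with no named state, and 11.9%, 35.8% and 77.3% among 15842 in all sorted cells. False calls made up 8.72% of calls in microglia-like, 4.44% in monocyte-like, 6.31% in macrophage-like, 27.7% in neutrophil-like, 8.47% in DAM-like, 9.66% in microglia-like cells with no named state and 1.19% in all sorted cells. A 1.5-fold change therefore went mostly unseen in every class as simulated. A simulated 1.5-fold change of the phagocytosis list was found in microglia-like, monocyte-like and macrophage-like cells with both the preset and the estimated correlation. The counts came from a single draw per class, with a single mean per gene and no batch or sex effects. The rates can therefore differ in the real design. Genes were simulated independently of one another, whereas the real disease-associated microglia list had an estimated correlation of 0.299 in microglia-like cells. The simulation therefore does not show what the estimated-correlation test can find in correlated lists.

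Other settings fixed beforehand were DESeq2, its size factors in edgeR, no low-count filter, no sex term, no batch C, batch A alone, each animal left out in turn, doublets kept, a filter of 1000 UMIs and 5% mitochondrial counts, equal numbers of cells per animal, Leiden resolution 1.5, no centring by batch, and camera with an estimated correlation or fry. Settings added after the data had been seen were the removal of cells with the highest doublet scores, no Harmony step, immune cells alone, clustering without DAM genes, and permutation of list means.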

Results

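Single-cell RNA sequencing was carried out on myeloid cells sorted from the brains of 12 5xFAD mice, a transgenic strain that lays down amyloid plaques. The mice were 5 months old. In 6 animals the nerves to the spleen had been severed (denervated), and 6 animals were controls that the labels name sham. The title of the series asks how the spleen's nerve supply bears on the exchange of signals between monocytes and microglia in the amyloid-laden brain. Cells positive for CD45 and CD11b were sorted, a gate that takes microglia, monocytes, macrophages and neutrophils, and the meninges and choroid plexus were left in the tissue. Animals are named as in the labels. They formed 3 batches of 4, each with 2 sham and 2 denervated animals. All animals of batch A were female. Batch B held 1 male and 1 female sham animal and 2 denervated males. In batch C both sham animals were female and both denervated animals male, so sex and group cannot be told apart within that batch. Over all batches, 5 of the 6 sham animals and 2 of the 6 denervated animals were female.

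The deposited matrices held 37525 cell barcodes, of which 36463 were kept, 19865 from sham and 16598 from denervated animals. Each animal gave 2002 to 4693 kept cells and a total of 4517484 to 29306392 unique molecular identifiers (UMIs, counted transcripts). Depth differed more between batches than between groups. The median UMI count per cell ran from 1267.5 to 1583.5 in batch A, from 1476.5 to 2122.5 in batch B and from 2799 to 5826 in batch C. Its mean over animals was 2356 ± 1344 in sham and 2673 ± 1769 in denervated animals (SD, n = 6 each).

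Microglia-like cells, the resident macrophages of the brain, were the most numerous class with 25240 cells, 878 to 4015 per animal. Within them, 3700 cells fell into DAM-like clusters led by Cst7, Lpl, Fabp5 and Spp1. DAM are the disease-associated microglia that gather at amyloid plaques. A further 20612 microglia-like cells had no named state, and homeostatic microglia were not set apart as a state. Clusters of 2189, 882 and 613 of these cells, from batches B and C, held 3 to 5 microglial markers among their leading genes, and none did in batch A. Neutrophil-like cells led by S100a8, S100a9 and Retnlg numbered 2518, monocyte-like cells 876 and border-associated macrophage-like cells led by Mrc1, F13a1 and Pf4 numbered 813. The monocyte-like class joined classical clusters led by S100a4, Plac8 and Ly6c2 and a non-classical cluster led by Adgre4, Ace and Itgal. Unnamed clusters held 10.3% ± 8.29 of the cells of sham and 10.2% ± 3.47 of those of denervated animals (SD, n = 6 each). Among these were clusters high in MHC class II genes and led by Mgl2 and Cd209a, which held too few of the fixed markers to be named, at 1.14% ± 0.933 in sham and 1.72% ± 0.837 in denervated animals. A cluster of 258 cells, 91.9% of them from batch B, led by H2-Eb1 and with Ms4a7 and Mrc1, held 2 macrophage markers and was also left unnamed, so the macrophage-like class and its shares by batch rest on the marker rule. The unnamed cells also held a cluster of 759 cells led by Acta2, Tagln and Myh11, genes of smooth muscle, 87.6% of them from batch A, 3 clusters of 148, 107 and 21 cells with 1 endothelial or mural marker each and 1 of 50 cells with an oligodendrocyte marker. Outside the gate's target, choroid plexus epithelium-like, endothelial, astrocyte-like and erythroid-like cells together made up 7.82% ± 7.74 in sham and 7.42% ± 7.60 in denervated animals, with 22.3% in Sham_586, which are lower bounds because those unnamed clusters are not counted. Clusters with markers of more than one class, set beside the microglia-like class, held 2.99% ± 2.39 in sham and 3.51% ± 2.73 in denervated animals. Clusters of low UMI counts held 1.17% ± 1.81 and 1.70% ± 2.74, and both kinds are part of the unnamed share.

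The first comparison asked whether the makeup of the sorted cells differed after denervation. DAM-like cells made up 17.2% ± 10.3 of the microglia-like cells of sham animals and 9.88% ± 5.99 of those of denervated animals (SD, n = 6 each). The batch means lay in the same order in every batch. They were 24.4% in sham and 13.5% in denervated animals of batch A, 20.3% and 12.4% in batch B, and 6.87% and 3.72% in batch C. The difference of -0.68 on the logit scale had an exact two-sided permutation p of 0.0278 and an adjusted p of 0.278 over 10 shares, so it did not pass. No single share could pass alone in this test, since the smallest possible p gives an adjusted p of 0.0926 over 10 shares. When the microglia-like cells were clustered without the DAM genes, the difference was -0.60 with an adjusted permutation p of 0.463, and over 22 alternatives the adjusted p ran from 0.0926 to 0.833. The genes that define these clusters are themselves compared between the groups, so the share and the DAM gene levels are not independent.

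Monocyte-like cells, the class named by the title of the series, made up 2.38% ± 0.987 of the sorted cells in sham and 2.47% ± 0.989 in denervated animals (SD, n = 6 each, logit difference 0.07, exact permutation p = 0.778, adjusted p = 0.864). The difference was 0.21, -0.17 and 0.16 in batches A, B and C. Classical cells, the Ly6c2-high monocytes that enter from the blood, made up 44.5% ± 19.3 of the monocyte-like cells in sham and 54.4% ± 19.6 in denervated animals (adjusted permutation p = 0.714), with batch differences of -0.28, 0.68 and 0.96. Microglia-like cells made up 68.4% ± 14.6 and 67.9% ± 9.18 of the sorted cells (adjusted permutation p = 0.870), and their batch differences were -0.08, -0.23 and 0.14. Macrophage-like cells made up 1.95% ± 1.01 and 2.61% ± 1.56 (adjusted permutation p = 0.714; 0.29, 0.68 and -0.26 by batch). Neutrophil-like cells made up 6.44% ± 8.14 in sham and 6.70% ± 4.33 in denervated animals (adjusted permutation p = 0.714; 0.96, 0.18 and 0.01 by batch), and Sham_627 alone had 22.8%. Lymphoid-like cells, which joined the T, B and natural killer cell clusters, made up 2.71% ± 3.64 and 2.73% ± 4.07 (adjusted permutation p = 0.714, with 0.50, 0.40 and -0.25 by batch). Among microglia-like cells, interferon-responsive cells made up 1.23% ± 0.271 in sham and 1.51% ± 0.727 in denervated animals (adjusted permutation p = 0.799; 0.34, 0.32 and -0.38 by batch), and proliferating cells 1.90% ± 0.715 and 2.77% ± 1.80 (adjusted permutation p = 0.714; 0.45, 0.44 and -0.34 by batch). Microglia-like cells with no named state made up 79.7% ± 10.9 and 85.8% ± 7.90 (adjusted permutation p = 0.417; 0.49, 0.36 and 0.64 by batch). The smallest p that the within-batch assignments can give is 0.00926. The gate and the depth gap between batches can both set these shares, which are shares of sorted and sequenced cells, not of the brain.

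**Figure D1:**
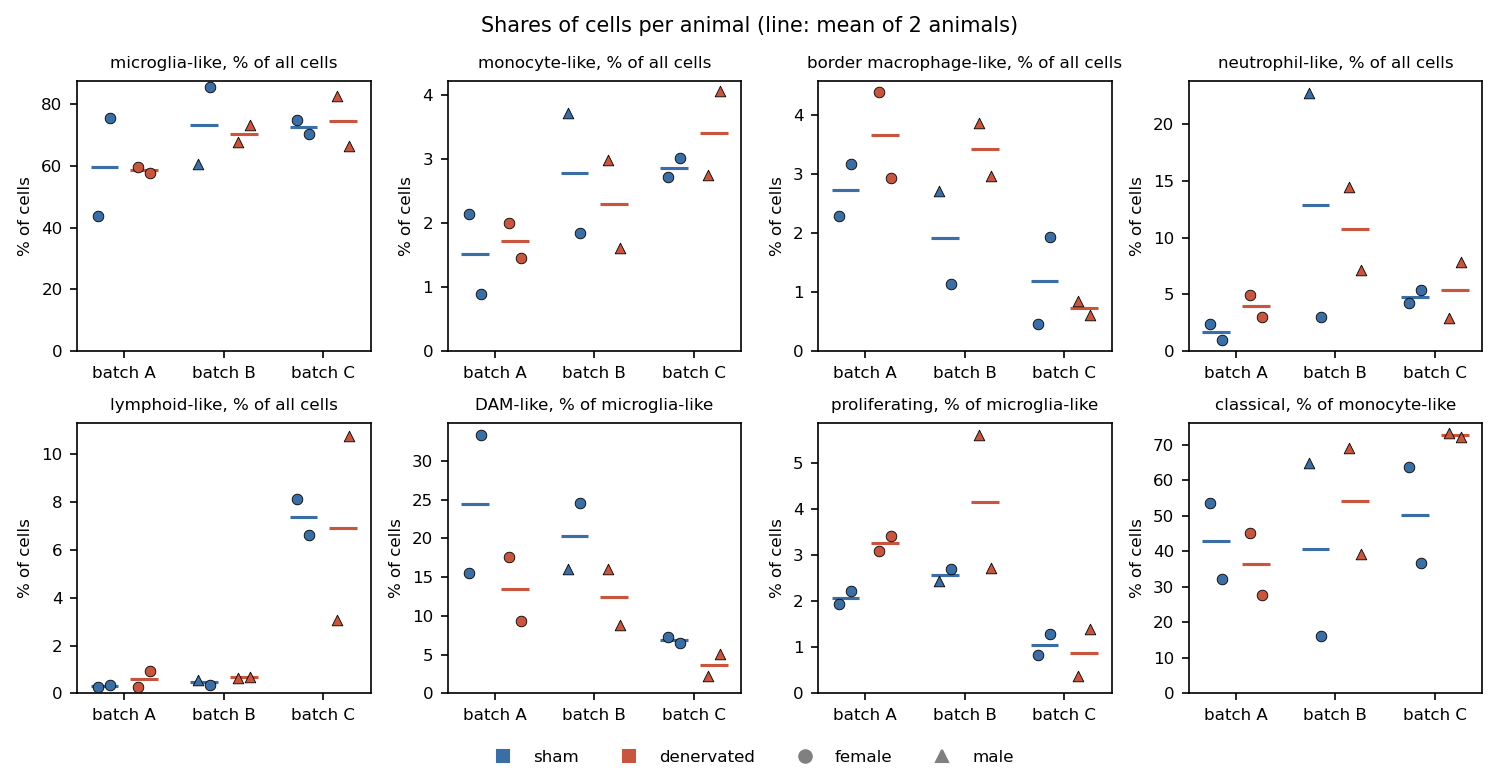
Shares of cell classes and microglia states per animal, in percent of the parent cells on the vertical axes, by batch on the horizontal axes. Blue points are sham and red points denervated animals, circles are female and triangles male, and lines mark the mean of the 2 animals of a group in a batch. The DAM-like share has its lower batch mean in denervated animals in each batch, with values of the 2 groups overlapping over all 12 animals.

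The second comparison asked which genes differed within microglia-like cells. The genes with the smallest p among those lower in denervated animals were Tnfaip3, which encodes the NF-kB inhibitor A20, the Gt(ROSA)26Sor transcript, Plaur, the urokinase receptor, and Apoe, the lipid carrier that DAM express highly. Plaur (chromosome 7, 24462484 to 24475968, mm10) stood at 52.9 ± 20.1 counts scaled to library size (CPM) in sham and 29.9996 ± 10.3 in denervated animals (SD, n = 6 each), a fitted log2 fold change of -1.02 ± 0.19 (SE), with batch differences of -0.79, -0.85 and -0.78. Apoe (chromosome 7, 19696109 to 19699188) stood at 5530 ± 2476 and 3413 ± 1460 CPM, a log2 fold change of -0.74 ± 0.17, with batch differences of -0.57, -0.75 and -0.78. Without TMM scaling, Apoe was also lower in neutrophil-like cells, at 4430 ± 862 CPM in sham and 2944 ± 981 in denervated animals. In macrophage-like cells it stood at 16130 ± 5381 and 17342.5 ± 2374 (n = 5 each). Its fall is therefore not set apart from background RNA. Tnfaip3 (chromosome 10, 19000910 to 19015657) stood at 60.7 ± 23.8 and 43.3 ± 13.4 CPM, a log2 fold change of -0.77 ± 0.14, with batch differences of -0.46, -0.53 and -0.34. Gt(ROSA)26Sor had a log2 fold change of -0.95 ± 0.18, with batch differences of -0.29, -0.85 and -0.17 and 42.2 CPM in Sham_627 against at most 18.5 in the other sham animals, and Gm15564 one of -0.65 ± 0.15, the latter with a batch C difference of 0.26, opposite to the fit. None passed the edgeR quasi-likelihood test, where Plaur, Tnfaip3 and Gt(ROSA)26Sor had an adjusted p of 0.369 and Apoe one of 0.896. By DESeq2, Plaur (-1.01, adjusted p = 0.0265), Apoe (-0.75, adjusted p = 0.0296) and Tnfaip3 (-0.78, adjusted p = 0.0343) passed.

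On the other side, the genes with the smallest p were Sema4b, a semaphorin, at 15.97 ± 4.96 CPM in sham and 22.8 ± 6.32 in denervated animals (log2 fold change 0.78 ± 0.18, SE, n = 6 each), and Hlf, a PAR-domain transcription factor, at 18.7 ± 7.48 and 37.1 ± 16.7 CPM (1.02 ± 0.26). Hlf differed by 0.97, 0.76 and 1.03 in batches A, B and C, and Sema4b by 0.71, 0.26 and 0.59. Dok3, an adaptor that restrains immune receptor signalling, had a log2 fold change of 0.39 ± 0.11, Ints10 of the Integrator complex 0.51 ± 0.15 and Zrsr1 0.57 ± 0.17. No adjusted edgeR p of these 5 genes was below 0.896. By edgeR's quasi-likelihood test, 0 of 13012 genes passed an FDR of 0.05, and DESeq2 called 3 genes. At an unadjusted p under 0.05 stood 518 genes, fewer than that threshold gives by chance alone, and the same held in every other class below. Without the low-count filter edgeR called 178 genes, a count set against other splits of the animals further below. With the filter, the edgeR count was 2 without Sham_645, which were Gm31597 and Lars2, and 1 without Denerv_951, which was Plaur.

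The panel of microglial genes chosen beforehand held no gene that passed the edgeR test. Lpl, lipoprotein lipase, stood at 177 ± 64.8 CPM in sham and 83.1 ± 48.7 in denervated animals (log2 fold change -0.95 ± 0.35), and the receptor Axl at 56.8 ± 12.3 and 37.5 ± 15.4 (-0.55 ± 0.26). The fold change of the cystatin gene Cst7 was -0.57 ± 0.50, of Spp1, osteopontin, -0.69 ± 0.54, of Itgax, CD11c, -0.40 ± 0.45, and of Tyrobp, the signalling partner of TREM2, -0.22 ± 0.21. Trem2 itself had -0.02 ± 0.16. The homeostatic genes P2ry12, an ADP receptor, and Tmem119 had 0.20 ± 0.14 and 0.21 ± 0.14, with 1843 ± 246 and 726 ± 205 CPM in sham animals against 1963 ± 372 and 790 ± 228. Cx3cr1, the fractalkine receptor, had 0.05 ± 0.13, Csf1r, the receptor for the survival factor CSF1, -0.08 ± 0.13 and Tgfbr1 0.01 ± 0.14. The cytokine genes Il1b and Tnf had -0.50 ± 0.37 and -0.21 ± 0.32. The interferon-induced genes Isg15 and Ifit3 had 0.35 ± 0.19 and 0.24 ± 0.30, and the MHC class II genes H2-Aa and Cd74 0.13 ± 0.58 and 0.03 ± 0.56.

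**Figure D2:**
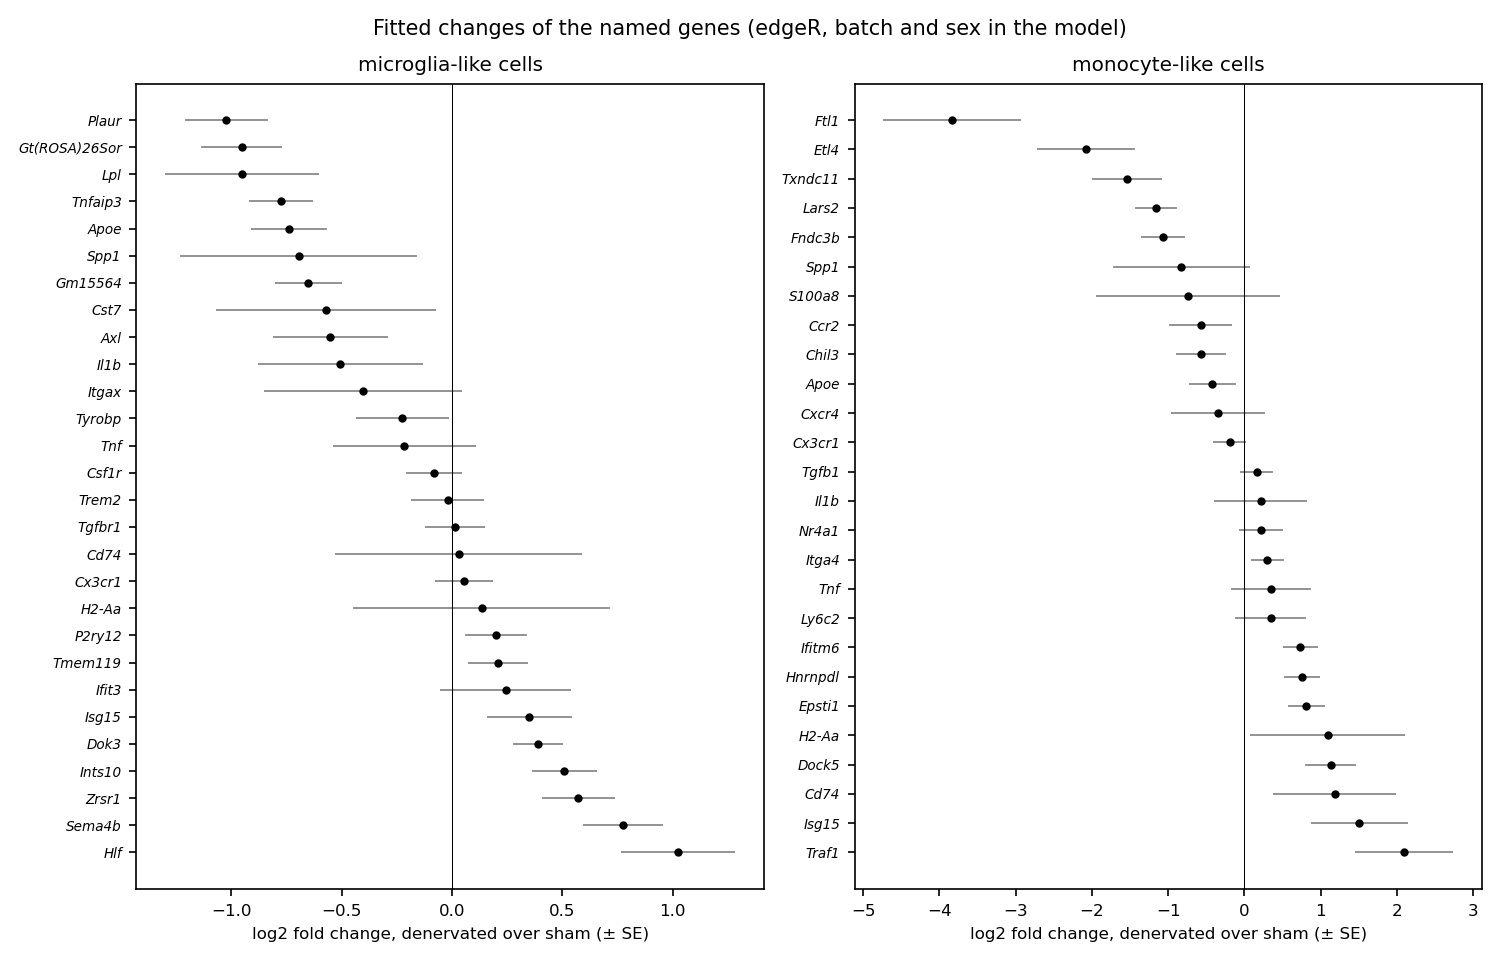
Fitted log2 fold change of named genes, denervated over sham, from edgeR on summed counts of microglia-like and monocyte-like cells on the horizontal axis, with bars of 1 standard error. Plaur, Apoe and Tnfaip3 lie below 0 in microglia-like cells, and Ftl1 at -3.83 in monocyte-like cells has the largest fold of those drawn.

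As a group, the DAM genes were lower in denervated microglia-like cells. All 27 measured members of the DAM list had a fold change below 0 in edgeR, with a median of -0.33 and batch medians of -0.32, -0.36 and -0.53 in batches A, B and C. Apoe, Lpl, Igf1 (-0.81 ± 0.34, an insulin-like growth factor) and Lilrb4a (-0.48 ± 0.18, an inhibitory receptor) had the smallest p. The list passed camera with its preset correlation (adjusted p = 4.34e-09) but not with an estimated correlation (adjusted p = 0.235) nor fry (adjusted p = 0.437). The mean log2 CPM of the list was 8.50 ± 0.755 in sham and 8.01 ± 0.866 in denervated animals (n = 6 each, difference -0.49, exact permutation p = 0.0185, adjusted p = 0.148 over 24 lists). None of the members was called over all genes, and 1, Apoe, was called when adjusted over the list alone. The median over the members was -0.26 in the values camera used and -0.10 without Sham_645. The median was -0.28 in microglia-like cells with no named state, where 26 of the 27 members were lower, and -0.12 in DAM-like cells, where 21 were. In DAM-like cells the mean log2 CPM of the list differed by 0.01 (exact permutation p = 0.917), with batch differences of -0.25, -0.00 and 0.30, so no fall was seen there in the raw means.

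Several lists tied to lipid handling and uptake fell with the DAM list by camera's preset test, each without passing with an estimated correlation. These were lipid efflux and droplet genes (10 of 16 lower, Plin2, a lipid droplet protein, -0.41 ± 0.16, adjusted p = 0.00783, and adjusted p = 0.235 with an estimated correlation), cholesterol synthesis (15 of 18 lower, Sc5d -0.57 ± 0.18, Insig1 -0.42 ± 0.20, adjusted p = 0.00195, and 0.475 with an estimated correlation) and phagocytosis receptors (17 of 20 lower, the scavenger receptor Msr1 -0.78 ± 0.20 and Axl, adjusted p = 0.00195, and 0.235 with an estimated correlation). Msr1 was the 1 phagocytosis receptor called when adjusted over the list alone. The lysosome list (26 of 33 lower, Asah1 -0.23 ± 0.10 and Cd63 -0.33 ± 0.18) had an adjusted p of 0.00247, and adjusted p = 0.548 with an estimated correlation. The anti-inflammatory and repair list (16 of 21 lower) had adjusted p = 0.00130, and 0.235 with an estimated correlation, with Msr1 and Igf1, which other lists also hold, at the smallest p and a batch C median of 0.10. Microglial receptors for monocyte signals were lower in 38 of 46 members, with Cd44, the hyaluronan receptor, at -0.86 ± 0.26, Notch1 at -0.43 ± 0.14 and C3ar1, the receptor of complement C3a, at -0.33 ± 0.11 (adjusted p = 7.28e-05, and adjusted p = 0.235 with an estimated correlation). The batch medians of that list were -0.08, -0.01 and -0.01.

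Other lists with a preset camera call concerned growth and handling of the cells. Glycolysis and hypoxia genes were lower in 19 of 21 members, with the glucose transporter Slc2a1 at -0.56 ± 0.18 and Ero1l at -0.45 ± 0.15 (adjusted p = 3.93e-06, and adjusted p = 0.261 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 58 of 58 members (median -0.19, adjusted p = 3.85e-05, and 0.608 with an estimated correlation). Immediate early genes, which enzymatic dissociation induces, were lower in 21 of 22 members (Btg2 -0.78 ± 0.28, Egr2 -0.56 ± 0.26, adjusted p = 2.01e-04, and 0.517 with an estimated correlation), with a batch C median of 0.03. Genes for monocyte ligands were lower in 31 of 45 members (adjusted p = 0.0227, and 0.545 with an estimated correlation). Mitotic genes were higher in 21 of 24 members (Cenpf 0.79 ± 0.26, Top2a 0.63 ± 0.31, adjusted p = 8.02e-05, and 0.545 with an estimated correlation), with batch medians of 0.54, 0.58 and -0.35.

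The remaining lists did not pass the preset test in microglia-like cells. Their adjusted camera p was 0.0506 for NF-kB and pro-inflammatory genes (18 of 27 lower, with Tnfaip3 called when adjusted over the list alone) and for complement, 0.107 for the type I interferon response, 0.111 for interferon gamma genes, 0.190 for homeostatic microglia (13 of 20 higher), MHC class I and oxidative phosphorylation, 0.219 for heat shock, 0.424 for monocyte migration, 0.541 for TREM2 signalling and 0.996 for MHC class II. The TREM2 signalling list had a median of 0.03 but a mean of -0.13 and a downward camera test, and its mean log2 CPM differed by -0.19 (exact permutation p = 0.00926, adjusted p = 0.111). That of the lipid efflux list differed by -0.23 with the same p, and that of glycolysis by -0.28 (exact permutation p = 0.0463, adjusted p = 0.278). Median, mean and test also differed in sign, each far from passing, for the homeostatic, NF-kB, anti-inflammatory, lipid efflux and oxidative phosphorylation lists in monocyte-like cells and for the MHC class I, NF-kB and anti-inflammatory lists in macrophage-like cells. In all, 12 of 24 lists passed with the preset correlation and 0 with an estimated correlation or by fry. The preset calls therefore rest on treating the members as nearly independent. By exact permutation of list means 0 passed as well, but no list could pass alone there. TREM2 signalling and lipid efflux, at the smallest possible p of 0.00926, had an adjusted permutation p of 0.111. Without Sham_627 the preset count was 4, and these lists are not 12 separate findings, since several of them share Apoe, Lpl, Igf1 and Msr1.

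**Figure D3:**
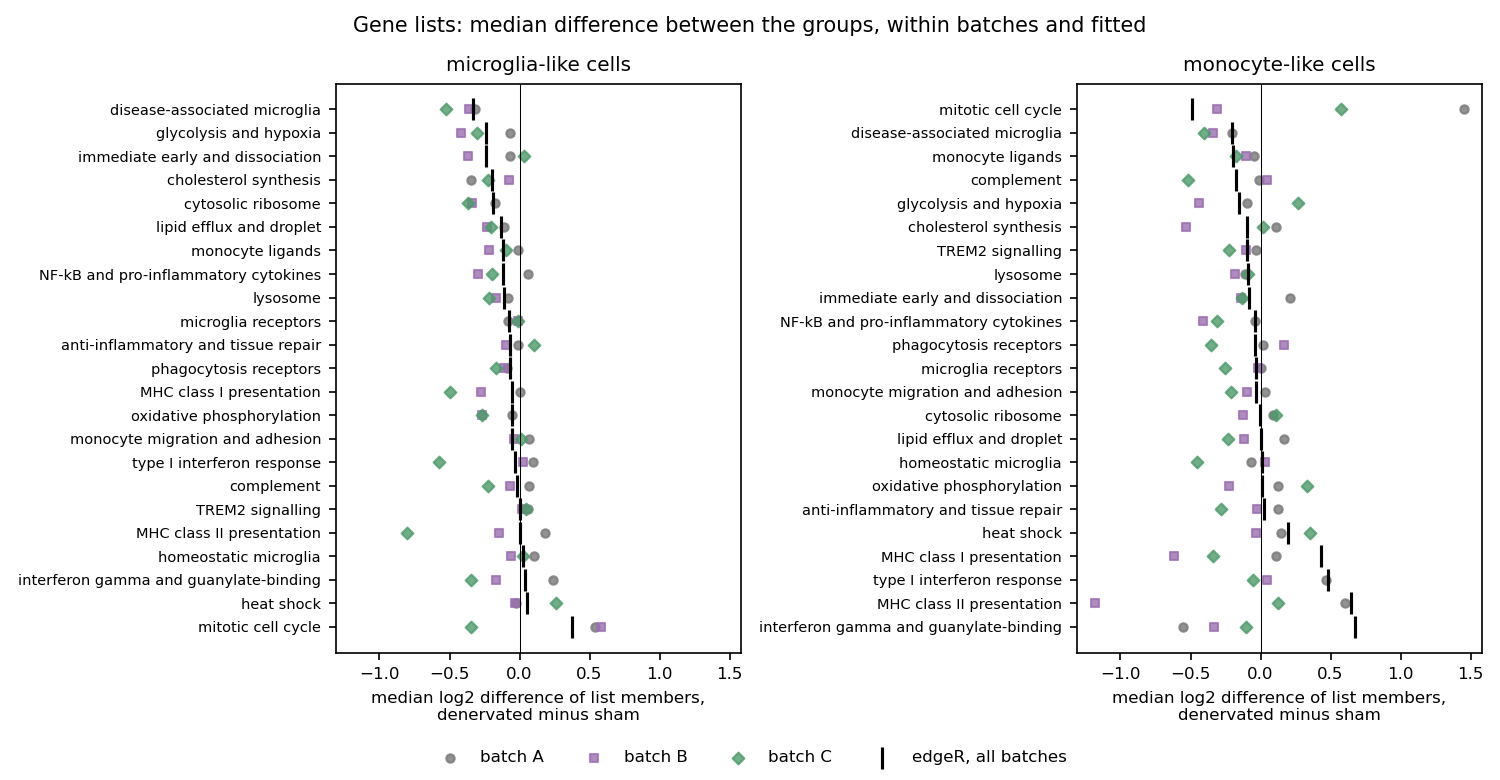
Median log2 difference, denervated minus sham, of gene lists in microglia-like and monocyte-like cells on the horizontal axis. Grey circles are batch A, purple squares batch B, green diamonds batch C and black bars the edgeR fit over all batches. The DAM list lies below 0 in all 3 batches in both classes, while the monocyte-like mitotic list runs from -0.31 to 1.45 by batch.

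Within the parts of the microglia-like class, Plaur, Tnfaip3, Gt(ROSA)26Sor, Sema4b and Hlf were again among the genes with the smallest p in cells with no named state. There, Plaur stood at 30.6 ± 13.8 CPM in sham and 17.0 ± 7.81 in denervated animals (log2 fold change -1.09 ± 0.19, edgeR adjusted p = 0.169), with batch differences of -0.68, -1.10 and -0.72. Tnfaip3 (-0.82 ± 0.17), Gt(ROSA)26Sor (-0.96 ± 0.20) and Rassf3 (-0.44 ± 0.10) followed, and Klc2, a kinesin light chain (0.66 ± 0.16), Sema4b (0.75 ± 0.20), Pxk (0.73 ± 0.20), Hlf (0.96 ± 0.27) and Chst8 (0.49 ± 0.15) were the counterparts on the other side. In edgeR 0 of 12344 genes passed, with 458 at an unadjusted p under 0.05, and DESeq2 called 2, Plaur (-1.08) and the kinase gene Prkcq (2.79). The edgeR count was 1 without Denerv_591 or without Sham_627, Sham_645 or Sham_949, and none of these calls was Plaur. The call was Gt(ROSA)26Sor without Denerv_591, the erythroid gene Hbb-bs without Sham_627, and Gm31597 without Sham_645 or Sham_949. In DAM-like cells the smallest p belonged to Zfp84 (1.03 ± 0.26), Lpgat1 (0.74 ± 0.20), Spata5 (0.65 ± 0.19), Lacc1 (0.50 ± 0.16) and Ranbp1 (0.45 ± 0.14) on one side and Btg2 (-0.63 ± 0.15), Gm15564 (-0.81 ± 0.20), Lars2 (-0.66 ± 0.17), Gm34455 (-0.96 ± 0.25) and the lamin gene Lmnb1 (-0.72 ± 0.21) on the other. In edgeR 0 of 9806 genes passed (323 at an unadjusted p under 0.05, 0 by DESeq2), and the count was 1 without Sham_645. The batch C difference of all 5 lower genes was opposite to the fit. Sham_627 had 669 CPM of Lars2 and 258.67 CPM of Gm15564 in DAM-like cells, against at most 219 and 86.6 in the other sham animals.

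The third comparison took monocyte-like cells. No gene passed, and the genes with the smallest p were led by Dock5, a regulator of cell shape, at 96.2 ± 69.3 CPM in sham and 125 ± 23.8 in denervated animals (log2 fold change 1.13 ± 0.33, n = 6 each), and by Lars2, the mitochondrial leucyl-tRNA synthetase, at 264 ± 158 and 206 ± 130 (-1.16 ± 0.27). Traf1, an adaptor of TNF receptors (2.10 ± 0.65), Ifitm6, an interferon-induced membrane protein (0.73 ± 0.23), Epsti1 (0.81 ± 0.25) and Hnrnpdl (0.76 ± 0.24) followed. On the lower side stood Ftl1, the ferritin light chain (-3.83 ± 0.91), Etl4 (-2.08 ± 0.64), Txndc11 (-1.54 ± 0.46) and Fndc3b (-1.07 ± 0.29). Of these, Hnrnpdl, Txndc11, Etl4 and Ftl1 kept 1 sign in all 3 batches. The chemokine receptor Ccr2, which brings classical monocytes into tissue, stood at 319 ± 236 and 456 ± 336 CPM, with a fitted fold change of -0.57 ± 0.41 opposite to these means. Ly6c2 stood at 444 ± 374 and 698 ± 630 CPM (0.35 ± 0.47). Cd74 and H2-Aa had fitted fold changes of 1.18 ± 0.81 and 1.09 ± 1.02, with mean CPM of 2511 ± 3398 and 460 ± 586.103 in sham and 1664 ± 1194 and 290 ± 190 in denervated animals. These sham means hold 9318 and 1643 CPM in Sham_646, against 606 to 2420 and 135 to 370 (369.521) in the other sham animals. Isg15 had 1.51 ± 0.63, Apoe -0.42 ± 0.31, Chil3 -0.56 ± 0.33, Itga4 0.30 ± 0.22, Cx3cr1 -0.19 ± 0.22, Tgfb1 0.16 ± 0.22, Nr4a1 0.22 ± 0.29, Spp1 -0.83 ± 0.90, S100a8 -0.74 ± 1.21, Cxcr4 -0.35 ± 0.62, Tnf 0.34 ± 0.53 and Il1b 0.21 ± 0.61. EdgeR called 0 of 5899 genes, with 200 at an unadjusted p under 0.05, and DESeq2 called 0. The class held 31 to 156 cells per animal, and the edgeR count was 1 without Sham_949.

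Gene lists in monocyte-like cells gave 8 of 23 calls with camera's preset correlation and 0 with an estimated correlation, where each of the 8 had an adjusted p of 0.534. The DAM list was lower in 20 of 25 members (adjusted p = 0.00135, and adjusted p = 0.534 with an estimated correlation), led by Ank (-0.49 ± 0.27) and the fatty acid binding protein Fabp5 (-0.43 ± 0.28), with batch medians of -0.20, -0.34 and -0.41. The mean of that list differed by -0.34 (8.90 ± 0.420 and 8.55 ± 0.497 log2 CPM, exact permutation p = 0.0463, adjusted p = 0.497). This list is not set apart from microglial RNA in these cells, since the microglial gene P2ry12 stood at 784 ± 322 CPM in monocyte-like and 1814 ± 174 in microglia-like cells of sham animals, here without TMM scaling. Cst7, a DAM gene, stood at 290 ± 223 in sham and 147 ± 151 in denervated animals in monocyte-like cells, at 349 ± 185 and 202 ± 133 in neutrophil-like and at 713 ± 486 and 440 ± 226 in microglia-like cells. Genes for monocyte ligands were lower in 19 of 29 members, among them Pdgfb, a growth factor (-0.98 ± 0.37), and Mif, a cytokine (-0.64 ± 0.27), with an adjusted p of 0.0111, and adjusted p = 0.534 with an estimated correlation. Their batch medians were -0.05, -0.11 and -0.18. Glycolysis genes were lower in 13 of 16 members (adjusted p = 0.0354, and 0.534 with an estimated correlation), with batch medians of -0.10, -0.44 and 0.26. Type I interferon genes were higher in 13 of 16 members (Isg15 and Irf7, 0.85 ± 0.42, adjusted p = 0.00135, and 0.534 with an estimated correlation), with batch medians of 0.47, 0.05 and -0.05.

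The fit and the raw differences went apart for 4 further monocyte lists. Interferon gamma genes were higher in 7 of 7 members in the fit (Tap1 0.94 ± 0.39, Irf1 0.68 ± 0.33, adjusted p = 3.89e-04, and 0.534 with an estimated correlation), but their batch medians were -0.55, -0.33 and -0.10. MHC class I genes were higher in 11 of 13 (H2-K1 0.55 ± 0.25, adjusted p = 3.89e-04, and 0.534 with an estimated correlation) with batch medians of 0.11, -0.62 and -0.34, and MHC class II genes in 8 of 8 (adjusted p = 0.0356, and 0.534 with an estimated correlation) with 0.60, -1.18 and 0.12. Mitotic genes were lower in 12 of 18 (Ube2c -1.68 ± 0.57, adjusted p = 0.0111, and 0.534 with an estimated correlation) with 1.45, -0.31 and 0.57. Without sex in the model the MHC class I median was -0.30 and the mitotic median 0.43, both opposite to the fit with sex. Without Sham_627 the preset count over all monocyte lists was 0, and without Denerv_636 it was 5. The other 15 lists had adjusted camera p values from 0.104 (complement) to 0.995 (NF-kB).

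Macrophage-like cells of the brain borders were compared in 10 animals with at least 20 such cells. Batch C gave only Sham_949, a female, and Denerv_951, a male, so its differences here rest on 1 animal per group. Btg2, an anti-proliferative immediate early gene, stood at 289 ± 119 CPM in sham and 136 ± 48.4 in denervated animals (log2 fold change -1.01 ± 0.23, n = 5 each, edgeR adjusted p = 0.386), with batch differences of -1.01, -0.95 and -1.13. The monocarboxylate transporter Slc16a7 (-1.02 ± 0.27), the NAD-consuming enzyme Cd38 (-1.06 ± 0.30), Gm42418 (-0.71 ± 0.19) and the neutrophil gene S100a9 (-1.16 ± 0.35) followed. Without TMM scaling, mean Gm42418 was 6926 CPM in batch A, 28800.5 in batch B and 6779 in batch C. Its highest value, 47011 CPM, was that of Sham_627. On the other side stood Ptgds, prostaglandin D2 synthase (1.37 ± 0.30), Fcgr2b, the inhibitory Fc receptor (0.74 ± 0.21), Eif3j1 (0.94 ± 0.25), Rps6ka5 (1.24 ± 0.35) and Npl (1.71 ± 0.47). Ptgds was among the leading genes of choroid plexus and endothelial clusters when cells were clustered without centring. The choroid plexus gene Ttr stood at 916 ± 931 CPM in macrophage-like cells of sham and 643 ± 845 in those of denervated animals, without TMM scaling. The Ptgds difference is therefore not set apart from background RNA. EdgeR called 0 of 4576 genes, with 204 at an unadjusted p under 0.05, and DESeq2 called 0. The edgeR count was 2 without Denerv_591 or Sham_645 and 1 without Denerv_628, and without sex in the model Btg2 was called (-1.08, adjusted p = 0.00223). None of 21 gene lists passed with the preset correlation, an estimated correlation or fry. The type I interferon list was higher in 14 of 18 members (adjusted p = 0.240), with batch medians of 0.36, 0.41 and 0.38. The count of lists was 5 without Sham_645, 4 without Sham_586 and 1 without Denerv_581 or Denerv_591.

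Neutrophil-like cells gave 2 calls. Igsf8, an immunoglobulin superfamily membrane protein (chromosome 1, 172261641 to 172319841), rose from 39.2 ± 24.5 CPM in sham to 66.5 ± 26.1 in denervated animals (log2 fold change 1.32 ± 0.26, n = 6 each, edgeR adjusted p = 0.0473), with batch differences of 1.87, 0.67 and 0.02. Vcan, a proteoglycan gene of classical monocytes, which is below the expression set for named genes and is given because there were only 2 calls, had 7.98 ± 11.6 and 4.51 ± 5.02 CPM (-2.93 ± 0.52, edgeR adjusted p = 0.0343), with batch differences of 0.00, -0.27 and -0.02. DESeq2 called 0 of the 10569 genes, and 331 had an unadjusted edgeR p under 0.05. In a single simulated draw of this class, without batch or sex effects, 27.7% of the calls were false, more than the FDR of 0.05 allows. F13a1, also a monocyte gene, had a fitted fold change of -1.39 ± 0.29 (edgeR adjusted p = 0.0807) against mean CPM of 37.3 in sham and 60.3 in denervated animals. The complement receptor gene C5ar2 had -1.66 ± 0.36, Gt(ROSA)26Sor -1.48 ± 0.35, Gm15987 -1.66 ± 0.42 and Olfml2b -1.38 ± 0.38. Lacc1 had 0.87 ± 0.25, the formin Diaph3 1.56 ± 0.45, the histone methyltransferase Ezh2 1.24 ± 0.35 and 4833420G17Rik 0.88 ± 0.26. The count was 0 without Sham_627 or Sham_645 or Denerv_628 or Denerv_956, and 8 without Denerv_636, 4 without Denerv_951 and 3 without Sham_646. Igsf8 was not called without Sham_586 or without Denerv_591, where F13a1 was, and without sex in the model neither Igsf8 nor Vcan was.

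Summed over all sorted cells, which needs no clustering, edgeR called 0 of 15842 genes, with 450 at an unadjusted p under 0.05, and DESeq2 called 0. Sema4b (0.61 ± 0.15), Ints10 (0.53 ± 0.14), Rnase6 (0.54 ± 0.15), Ezh2 (0.41 ± 0.11) and Hlf (0.91 ± 0.26) had the smallest p among genes higher in denervated animals. Ftl1 (-3.02 ± 0.68), Gt(ROSA)26Sor (-0.86 ± 0.21), Rassf3 (-0.41 ± 0.10) and Gm15564 (-0.58 ± 0.15) had the smallest p among those lower. The edgeR count was 3 without Sham_645. RNA of other cell classes was present within classes and differed between the animals. Ttr, the transthyretin gene of the choroid plexus, stood at 475 ± 431 CPM in microglia-like cells of sham and 331 ± 355 in those of denervated animals, with 1211 in Sham_586. P2ry12 stood at 1213 ± 214 CPM in neutrophil-like cells of sham and 1093 ± 352 in those of denervated animals. The neutrophil gene S100a8 reached 97.6 ± 115 CPM in microglia-like cells of sham and 66.1 ± 59.8 in those of denervated animals.

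Ftl1 (chromosome 7, 45457944 to 45459884), the light chain of the iron store ferritin, had a large fold change in several classes and was followed in microglia-like cells after its values were seen. It stood at 657 ± 463 CPM in sham and 98.4 ± 36.3 in denervated animals (n = 6 each, log2 difference -2.38, exact permutation p = 0.00926, the smallest possible here). The 6 sham animals were not alike, at 1056 and 141 CPM in batch A, 1176 and 162 in batch B and 958 and 452 in batch C, while the denervated animals ran from 45.0 to 151. Counts for Ftl1-ps1, a near-identical copy (chromosome 13, 74399694 to 74407346), were 1662 ± 1604 and 1963 ± 983 CPM (log2 difference 1.30, exact permutation p = 0.185), with 13.6 CPM in Sham_948 against 502 to 4318 in the other sham animals, so 1 animal weighs heavily in that difference. The sum of the pair was 2319 ± 1317 and 2061 ± 1010 CPM (log2 difference -0.14, exact permutation p = 0.509). The level of Ftl1 alone is therefore uncertain wherever it is given.

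**Figure D4:**
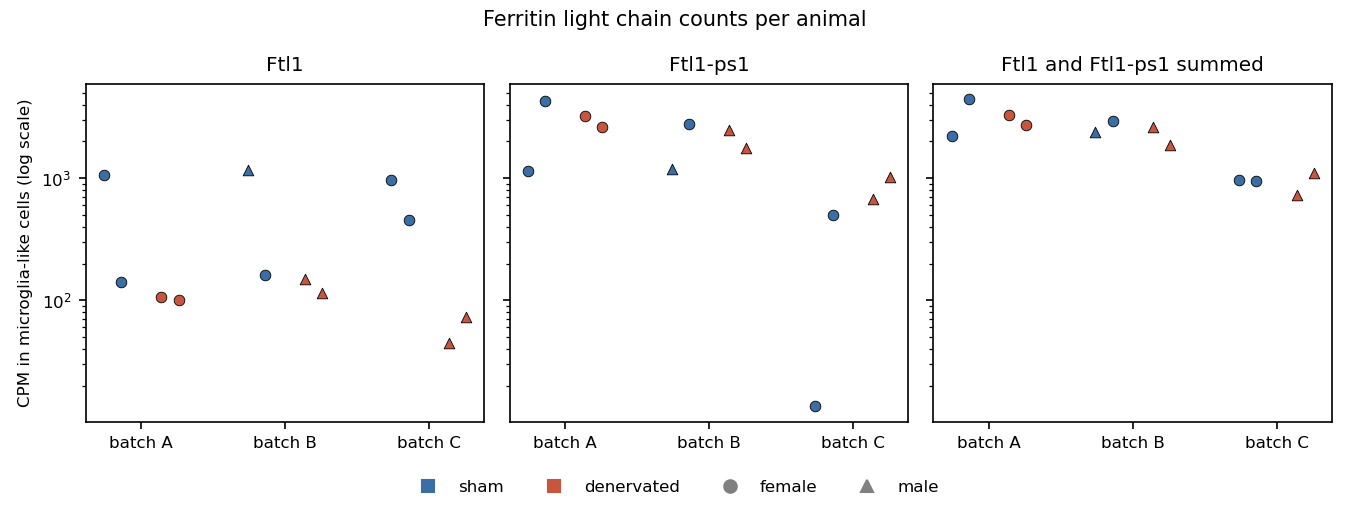
CPM of Ftl1, of its copy Ftl1-ps1 and of their sum in microglia-like cells, 1 point per animal on a log axis, by batch. Ftl1 spans 141 to 1176 in sham and 45.0 to 151 in denervated animals, and the sum spans 954 to 4458 in sham and 723 to 3318 in denervated animals.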

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

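The values given here were found by a fixed rule, Dixon's test of the highest or lowest of the 5 or 6 animals of a group, and no explanation was tested for them. Of 244 groups, 20 held such a value, against about 1 in 20 groups by chance, a rate that takes the animals of a group as alike although they come from 3 batches.

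Sham_627 stood apart most often. It had 22.8% neutrophil-like cells, against 0.938% to 5.37% in the other sham animals, and 288 CPM of Spp1 in microglia-like cells, against 20.3 to 119. Its Gt(ROSA)26Sor level was 42.2 CPM in microglia-like cells, 39.6 in microglia-like cells with no named state and 42.0 (42.0498 unrounded) in all sorted cells, against at most 18.5, 18.2 and 26.3 in the other sham animals. In DAM-like cells it had 258.67 CPM of Gm15564 and 669 CPM of Lars2, against at most 86.6 and 219, and in monocyte-like cells 1766 CPM of the neutrophil gene S100a8, against at most 258.

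Further animals stood apart in monocyte-like cells. Sham_646 had 9318 CPM of Cd74, 1643 CPM of H2-Aa and 31.5 CPM of Fndc3b, against 606 to 2420, 135 to 370 (369.521) and 128 to 185 in the other sham animals. Denerv_581 had 3921 CPM of Cd74 and 8728 CPM of Apoe, and Sham_645 had 8610 CPM of Apoe. Denerv_628 had 2013 CPM of S100a8, and Sham_949 had 155 CPM of Cxcr4. In macrophage-like cells Denerv_951 had 172 CPM of Slc16a7, against at most 94.6. Gt(ROSA)26Sor in Denerv_581 was 19.3 CPM in all sorted cells, the highest of its group, and 7.57 in microglia-like cells with no named state, the lowest. Denerv_956 had 10.8% lymphoid-like cells, against 0.2498% to 3.06% in the other denervated animals.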

How the results depend on the processing

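Alternatives chosen after the results were seen were the removal of cells with high doublet scores, no Harmony step, immune cells alone, clustering without DAM genes and permutation of list means. Without the low-count filter the genes past the edgeR threshold were 178 in microglia-like (0 with it), 1 in monocyte-like, 2 in macrophage-like, 14 in neutrophil-like (2 with it), 0 in all sorted, 2 in DAM-like cells and 32 in microglia-like cells with no named state. Of the 178, 173 were also tested with the filter, so the filter moved their adjusted p and not only their being tested. DESeq2 called 3 in microglia-like, 0 in neutrophil-like and 2 in cells with no named state. Without batch C the counts were 1 in microglia-like (Plaur), 7 in neutrophil-like and 1 in DAM-like cells. In batch A alone they were 1 in microglia-like (the erythroid gene Hba-a1), 0 in neutrophil-like, 1 in DAM-like cells (Bank1) and 1 in cells with no named state (the erythroid gene Hbb-bs). Without sex they were 1 in macrophage-like and 1 in neutrophil-like cells, the latter Diaph3, so that neither Igsf8 nor Vcan was called. The neutrophil-like count was 0 with the strict cell filter and 0 without Harmony. The cause was not tested for any of these. Leaving out 1 animal at a time gave 0 to 2 in microglia-like, 0 to 1 in monocyte-like, 0 to 2 in macrophage-like, 0 to 8 in neutrophil-like, 0 to 3 in all sorted, 0 to 1 in DAM-like cells and 0 to 1 in cells with no named state.

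Gene lists past camera's threshold, 12 in microglia-like and 8 in monocyte-like cells, were 0 and 0 with an estimated correlation, 0 and 0 by fry and 0 and 0 by permutation of list means, in which no list could pass alone. Leaving out 1 animal gave 4 to 17 in microglia-like, 0 to 10 in monocyte-like and 0 to 5 in macrophage-like cells, and without sex the macrophage-like count was 5. Without sex the monocyte-like MHC class I median was -0.30 and the mitotic median 0.43, both turned round. Of 1099 pairs of list and alternative, 927 stayed on the same side, 61 newly passed, 109 no longer passed and 2 reversed. Of 2306 pairs for 106 named genes, 2250 stayed, 46 newly passed, 10 no longer passed and 0 reversed, while 59 changed sign without a call. Igsf8 in neutrophil-like cells was the only named gene past the threshold to begin with. The 10 losses are therefore all of Igsf8, and nearly all pairs that stayed were of genes not called in the first place.

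None of 219 share alternatives passed, with a smallest adjusted p of 0.0926, and 14 changed sign. With batch and sex in a linear model the logit difference was 0.23 for microglia-like, -0.10 for monocyte-like and -0.41 for classical over monocyte-like cells, and in batch A alone the last was -0.28, each opposite to the value reported; the cause was not tested. Leaving out 1 animal gave -0.28 to 0.17 for microglia-like, -0.0820 to 0.22 for monocyte-like, -0.00302 to 0.47 for macrophage-like, -0.00782 to 0.44 for lymphoid-like, -0.0563 to 0.25 for interferon-responsive and -0.0287 to 0.40 for proliferating cells. The DAM-like difference stayed below 0 in each alternative run. Homeostatic microglia genes were not run, because no such state was set apart and only clusters of batches B and C held 3 or more microglial markers; cells with no named state took their place. A dendritic-like share was not run, because no cluster met the marker rule. No paired analysis was possible because the groups share no replicate numbers. Depth alone did not rank the classes, since a simulated 2-fold change was recovered for 34.3% of genes in monocyte-like cells, whose sums started at 57335 counts, and for 35.8% in all sorted cells.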

Other observations

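The tests of the DAM pattern on cell mix, sex and dissociation, all tests of Ftl1, and the splits without a low-count filter were chosen or changed after results had been seen.

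The neutrophil-like fit without batch C called 7 genes, of which Igsf8 and Vcan were also called over all batches. Ctsg, the granule protease cathepsin G of immature neutrophils, had a log2 fold change of 3.50 ± 0.59, Ms4a3, a gene of granulocyte and monocyte progenitors, 2.01 ± 0.37, and Nkg7, a gene of cytotoxic lymphocytes, 2.36 ± 0.48 (SE, 8 animals). The monocyte genes Vcan, Fn1 and F13a1 had -2.71, -2.05 and -1.34 in the same animals.

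Chance cannot be excluded for any value above 0 that was tested by other splits of the 12 animals within batches. Where the real count was 0 every split is as large by construction, and the split test says nothing. In microglia-like cells 0 genes were called and other splits gave up to 3 (60 of 60 drawn splits as large). Without a low-count filter 178 genes were called and another split gave 537 (7 of 40), which may reflect a structure among the animals, though none was tested for or identified. For the 12 microglia-like lists, another split gave 18 (13 of 60), and for the DAM median of 0.259 away from 0 another gave 0.459 (10 of 60). In monocyte-like cells the real values were 0 genes and 8 lists, and the highest others 9 and 12 (60 and 31 of 60). In macrophage-like cells they were 0 genes and 0 lists against 3 and 8 (36 and 36 of 36). Neutrophil-like cells had 2 genes against 37 (24 of 60), all sorted cells 0 against 0 (60 of 60) and DAM-like cells 0 against 5 (60 of 60). Microglia-like cells with no named state had 0 against 113 (60 of 60), which again may reflect a structure that was not tested for or identified.

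The DAM genes were lower in denervated microglia-like cells, and their list passed camera with its preset correlation. It did not pass with an estimated correlation (adjusted p = 0.235), by fry (adjusted p = 0.437) or by permutation of list means (adjusted p = 0.148). Besides denervation and chance, which is not excluded, 3 explanations were weighed. The sex of the animals stays open. With batch and sex in a linear model the group coefficient of the list's mean was -0.401 (exact permutation p = 0.0463), a test that replaced one on batch A alone. That p can be too small, because sex stayed fixed in the permutation and follows the real groups more closely than most splits. No range without single animals was computed for it. In batch A, where all animals were female, the list's mean differed by -0.45 (2 animals per group). Fewer DAM-like cells stays open, because in cells with no named state the list kept a share of 0.842 of its median, but 0.452 to 1.14 without single animals, on both sides of a bound of 0.8, and these cells still held clusters of 144 and 47 cells led by DAM genes. The dissociation response also stays open. With the immediate early list as a covariate a share of 0.824 of the difference was kept. Without single animals it was 0.632 to 0.940, on both sides of the bound of 0.8. In batch C the DAM list's mean differed by -0.635 and that of the immediate early list by -0.00482, so the fall there did not go with the latter. Both means were lower in batches A and B. Denervation itself stays among the open explanations.

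A low Ftl1 in denervated microglia-like cells was weighed against sequence differences between animals. Denervation as the whole cause is argued against, because in 2 of 3 batches the 2 sham animals differed by more than the groups did (log2 gaps of 2.91 and 2.86, and 1.08 in batch C). A candidate explanation is that reads were shared with Ftl1-ps1, since the sum of both differed by -0.142 against -2.38 for Ftl1. A strain variant near Ftl1 may decide which copy takes the reads, as 4 of the 20 genes most correlated with Ftl1 in either direction across animals within batches (Gm31597 and 5430431A17Rik with it, Gm15545 and Zfp473 against it) lie within 1 Mb of it, where 16 of 1658 ranked genes lie (exact hypergeometric p = 2.56e-05 across genes, which are not independent). Of the 20 genes, 7 lie on chromosome 7, among them Numbl, Fxyd1 and Lgi4 outside that window. The share of all ranked genes on that chromosome was not counted. Apoe and Plaur also lie on chromosome 7, and whether they follow such a variant was not tested.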
